A study of Sus scrofa domesticus with 4 samples.

How the data were processed

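Gene expression was measured on 4 two-colour oligonucleotide arrays. Each array carried RNA from anterior pituitary cells of mature gilts cultured with recombinant human adiponectin and RNA from untreated control cells. Per the labels' protocols, pituitaries of 4 gilts were taken in the mid-luteal phase, on days 10 to 12 of the oestrous cycle. One characteristic in the labels calls the same days a period of pregnancy, and the protocol's wording was followed here. The dispersed cells were precultured for 48 h and incubated for 24 h without serum, with or without adiponectin at 10 µg/ml. The labels do not say which gilt is on which array or that both RNAs of an array came from 1 gilt. The p-values of single probes thus measure the spread between these 4 arrays. The labels of the channels put the treated RNA in Cy5 (red) on arrays 1 and 3 and in Cy3 (green) on arrays 2 and 4, and these labels set the direction of each ratio. The wording of the labelling protocol differs, with control RNA in Cy3 and treated RNA in Cy5. That reading was run as an alternative.

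The arrays were scanned and quantified with Agilent Feature Extraction 10.7.3.1 on array design 026440, per the file headers. All 4 arrays lay on 1 slide and were scanned together, so no slide or scan separates them. Batches of culture or labelling are not stated in the labels. The deposited scanner files hold linear intensity values per spot (median foreground and local background per channel), flags for outlying, saturated and dim spots, and a log10 ratio of red over green, per the file headers. The deposited series matrix holds a log2 ratio per probe. It was set against the scanner's processed signals, and 99.99% of probes lay within 0.01 of their log2 ratio on each array, with the sign turned on arrays 2 and 4. Its scale is thus known, and its direction of treated over control follows the labels of the channels. Its columns were not centred, with medians of -0.04, 0.08, 0.04 and -0.05 on arrays 1 to 4.

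The plan, fixed before the data were examined, named the mean foreground signal. The files used here hold the median, which was used in its place. The background was corrected with normexp (offset 50), and the log2 ratios were normalized by loess within each array, with control spots at weight 0. On the first run, normexp failed on array 2. At 1 corner of that array 11 spots had a very high local background, and with them the fitted background SD was 1104 in red and 1485 in green, against 2.03 and 2.47 without them and the other spots of uneven background. This pressed the ratios of dim probes on array 2 towards 0, with a median absolute deviation of 0.008 against 0.15 to 0.17 on the other arrays. Spots whose local background the scanner software flagged as uneven (939 to 1350 of 43803 per array) were therefore treated as outlier-flagged and left out of the normexp fit and of all values. This choice was made after the results of the first run were seen, from the fitted background and the spread of the ratios, and before any test was run under it. The first run is given as an alternative. The spots flagged on 2 or more arrays were brighter than the rest, with a median signal of 949 against 108, so some of the most abundant transcripts were lost. The probe of CGA, the common alpha subunit, was lost on 4 of 4 arrays.

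Spots of 1 probe were averaged. A probe was tested if it was well above background in the treated channel or in the control channel on at least 3 of 4 arrays and had a value on at least 3 arrays. This kept 25912 of 43603 probes, of which 875 had 3 arrays. No spot was saturated, and 29 to 45 spots per array carried a feature outlier flag. Between 25174 and 29845 probes per channel were well above background. The number of arrays limits the precision. Tests used limma 3.58.1 in R 4.3.3: a linear model of the red over green log2 ratio with a dye term and a treatment term (+1 where treated RNA was red and -1 where it was green), moderated with eBayes, two-sided, with Benjamini-Hochberg adjustment over all tested probes and a threshold of 0.05. The pairing of treated and control RNA comes from their sharing an array. The intervals printed are 95% intervals of that model.

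The files used here pair probes with accessions. Gene symbols were taken by unversioned accession from RefSeq annotation of the assembly Sscrofa11.1, used for names only. Of the 43603 probes, 5578 matched, 76 of them genes with a provisional symbol, and 38025 stayed unnamed. The tested probes covered 1935 named genes. A gene was represented by its brightest tested probe, and a sign that differed in its other probes is stated for the genes named. Gene lists (27, of pathways, hormones, receptors and markers of cell types) were written before the data were examined, and 26 had at least 3 tested genes. Lists were tested with camera, with a preset correlation of 0.01 and with an estimated one, and with fry, each adjusted over the 26 lists, using genes measured on all 4 arrays. With the preset correlation, camera sets the members of a list against the other genes, so its p-values do not measure the spread between arrays. The SE printed with the mean of a list comes from that spread.

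The named genes followed a rule fixed in advance: genes past the threshold with 1 sign on every array (there were 0), then the 24 genes of smallest p with 1 sign on all 4 arrays, given as values; every measured pituitary hormone with ADIPOR1, ADIPOR2, CDH13 and APPL1; and up to 4 members of smallest p of each other list. Genes named outside the rule are said to be so, and some genes under it are not reported here.

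The probe test was tested on simulated data made from the adiponectin comparison (25037 probes, 50 planted changes per fold size and simulation). It recovered 1.2% of 1.2-fold changes, 17.6% of 1.3-fold, 88.6% of 1.5-fold and 99.8% of 2-fold changes, with a mean of 4.4 false calls per simulation. The planted folds are on the scale of the ratios with the offset. All fold sizes were planted in the same simulation, and the larger changes loosen the Benjamini-Hochberg threshold for the smaller ones. These rates thus do not give the recovery of a lone change, which would face a stricter threshold. The list test was tested on 20 simulations. With a planted shift of 0.1 in the inflammatory list, camera called it in 20 with the preset correlation, in 0 with an estimated one, and fry in 1. Without a shift, 0 lists were called. Noise was drawn independently for each probe or gene, so these counts do not cover lists whose members vary together.

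The alternatives tried were: no background subtraction, normexp without an offset, the scanner software's log ratio, the series matrix, median centring, scaling between arrays, no dye term, separate channels without the array pairing, other filters on dim probes, outlier-flagged spots kept, saturated spots left out, eBayes with trend and robust settings, other thresholds, the mean of a gene's probes, and each array left out in turn. Those chosen after seeing the data were treated RNA taken as Cy5 on every array and normexp fitted on all spots.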

Results

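The transcriptome of porcine anterior pituitary cells was compared after 24 h with and without adiponectin, a hormone of adipose tissue, at 10 µg/ml. Primary cells of gilts in the mid-luteal phase were used, and treated and control RNA were hybridised together on 4 two-colour arrays. The treated RNA carried Cy5 on 2 arrays and Cy3 on 2. Between 25174 and 29845 probes per channel were well above background, and 25912 probes were tested. Values are log2 ratios of treated over control cells from the fit with a dye term (n = 4 arrays unless stated). Values on single arrays are not corrected for dye.

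The first question was which transcripts differed between adiponectin-treated and control cells. The lowest ratio among the genes with 1 sign on all arrays was that of AMCF-II, a porcine CXC chemokine, at -0.36 (0.778-fold, 95% interval -0.51 to -0.21), with single arrays from -0.43 to -0.28. The cytokine genes IL1A and IL6 had ratios of -0.27 (-0.43 to -0.10) and -0.22 (-0.37 to -0.07), and the fitted values of the 3 tested probes of IL6 were all below 0. The adhesion molecule gene SELP had a ratio of -0.23. On the other side, AMY2, an amylase gene, had a ratio of 0.23 (0.08 to 0.38), and the fitted values of all 23 of its probes were above 0. The sign on single arrays is that of the brightest probe: the mean over probes was 0.12 on array 1 for IL6 and -0.02 on array 2 for AMY2. None of these genes passed the threshold. They were chosen for a small p and 1 sign on all arrays, so their intervals tend to leave out 0. With treated RNA taken as Cy5 on every array, as the labelling protocol reads, the ratios were -0.02 for AMCF-II, 0.16 for IL1A, 0.09 for IL6, -0.09 for SELP and 0.03 for AMY2.

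In the limma fit, 0 of 25912 probes had an adjusted p under 0.05, and the smallest adjusted p was 0.9999. At an unadjusted p under 0.05 there were 717 probes, 270 with higher and 447 with lower values, where chance gives 1296. The fitted ratios ran from -0.51 to 0.63. The 95% interval lay within a 1.5-fold change in either direction for 99.8% of probes and within a 1.2-fold change for 78.1%. These intervals hold for ratios with the offset of 50, which lie nearer 0 for dim probes. They thus do not bound the fold changes of dim transcripts. The count rested on all 4 arrays: with 3 arrays it was 0 without array 1, 720 without array 2, 1 without array 3 and 828 without array 4. In these fits 1 array alone carries its dye orientation, and the residual spread comes from the remaining pair of arrays alone.

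Of the 24 genes taken by smallest p, 14 had higher and 10 lower values in treated cells, and 23 are named here. With treated RNA taken as Cy5 on every array 13 of the 24 had the opposite sign. Read that way, the ratio is the dye term of the fit, so a mix of signs can arise under either reading. The choice of these genes and their direction rest on the channel labels, which the series matrix follows. Besides those above, the higher ones included ALOX5AP, needed for leukotriene synthesis, at 0.23, HOPX at 0.20, the troponin genes TNNC1 at 0.19 and TNNT1 at 0.19, SOCS2, an inhibitor of cytokine signalling, at 0.19, and LTF, which encodes lactoferrin, at 0.15. TCF7L2, a transcription factor of the Wnt pathway, PTGDS, HAPLN1, DNASE1, ADAP1 and TTL lay between 0.13 and 0.17. The lower ones included SLC7A2, a transporter of cationic amino acids, at -0.19, the mitotic genes CDC20 at -0.18 and SPAG5 at -0.16, EIF2AK2, an interferon-induced kinase, at -0.17, and the ribosomal protein genes RPL10 and RPS3A, both at -0.14. The other probes of ADAP1 and RPS3A and 1 of the 3 probes of TCF7L2 had the opposite sign. With the mean of a gene's probes, 6 of the 24 lay nearer 0 by over 1.5-fold: ALOX5AP at 0.10, HOPX at 0.09, TCF7L2 at 0.06, ADAP1 at 0.05, SPAG5 at -0.09 and RPS3A at -0.06. The control signal of HAPLN1 was well above background on 1 of 4 arrays. With the scanner software's log ratio the values were 0.74 for HAPLN1, 0.58 for TNNC1, 0.43 for ADAP1 and 0.30 for SOCS2. They were -0.52 for SLC7A2, -0.41 for SELP and -0.05 for RPS3A. In the series matrix RPS3A had -0.00590 and RPL10 -0.05.

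**Figure D1:**
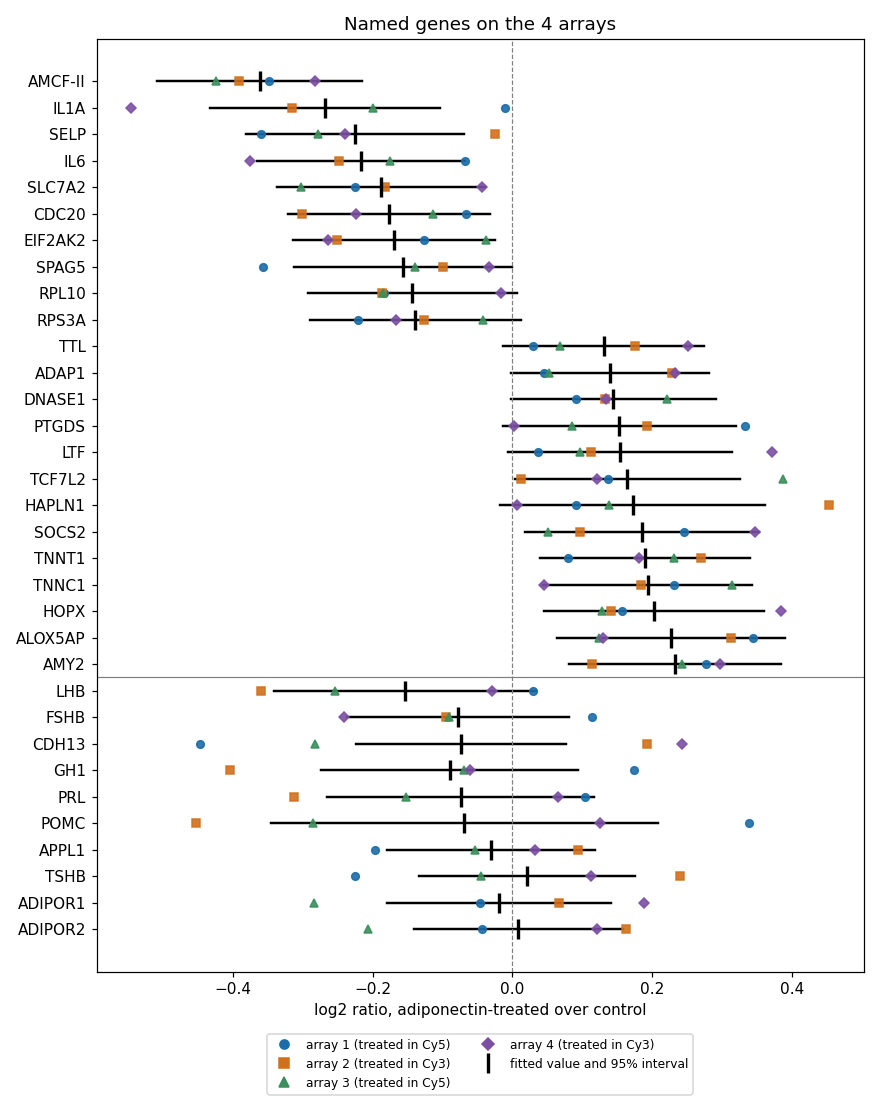
Log2 ratio of adiponectin-treated over control cells (horizontal axis) for 23 of the 24 genes of smallest p with 1 sign on all 4 arrays (above the grey line) and for the pituitary hormones and adiponectin receptor genes (below it); symbols are single arrays, black bars the fitted value with its 95% interval. AMCF-II lies between -0.43 and -0.28 on the 4 arrays, and the single arrays of the hormone genes lie on both sides of 0.

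The second question was whether the hormones of the gland and the receptors of adiponectin differed. Of the 6 tested pituitary hormone genes, 5 had lower values and 1 a higher value. The ratio of LHB, the beta subunit of luteinizing hormone, was -0.15 (-0.34 to 0.03), that of FSHB -0.08 (-0.24 to 0.08), of GH1 -0.09 (-0.27 to 0.09), of PRL -0.07 (-0.27 to 0.12), of POMC -0.07 (-0.35 to 0.21) and of TSHB 0.02 (-0.13 to 0.18). For LHB, PRL and POMC the brightest probe was the one nearest 0. Their lowest probes had fitted ratios of -0.20, -0.15 and -0.245, and the other hormone genes had 1 tested probe each. Each interval printed for the brightest probes held 0, and the list as a whole was not called (mean -0.07 ± 0.08, SE, adjusted p = 0.0683 by camera with the preset correlation, 0.879 with an estimated one). With the preset correlation it was called in 3 of 14 planned settings: without background subtraction, without the dye term and with the mean of a gene's probes (adjusted p = 0.0283, 0.0342 and 0.0437 by camera). With median centring its mean was 0.000649 (adjusted p = 0.401 by camera). It was also called without array 1 or 4, with means of -0.13 and -0.13, and had means of -0.02 and -0.01 without array 2 or 3. With treated RNA taken as Cy5 on every array, the ratios were 0.04 for LHB, 0.09 for FSHB and 0.14 for GH1. Those of PRL, POMC and TSHB were then 0.05, 0.095 and -0.16, so each hormone gene had the opposite sign. The receptor genes ADIPOR1 and ADIPOR2 had ratios of -0.02 (-0.18 to 0.14) and 0.01 (-0.14 to 0.16). CDH13, which encodes T-cadherin, an adiponectin-binding protein, had -0.07, and APPL1, an adaptor of the receptors, -0.03. The other probes of ADIPOR1 and APPL1 had the opposite sign, at 0.03 and 0.09.

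Gene lists fixed in advance were then compared. By camera with the preset correlation, 4 of 26 lists were called, each lower in treated cells, and 0 were called higher. With an estimated correlation 0 lists were called, with an adjusted p of 0.879 for each of the 4, and fry called 0 lists (smallest adjusted p = 0.657). Of the 28 tested genes of the NF-kB and inflammatory response, 20 had lower and 8 higher values (mean -0.06 ± 0.03, SE, adjusted p = 0.00611). IL1A and IL6 belong to it, with the chemokine gene CXCL8 at -0.26 and the prostaglandin synthase gene PTGS2 at -0.22, and 6 of its members had an unadjusted p under 0.05. CXCL8 and PTGS2 were above 0 on array 1, and with 1 array left out they ran from -0.37 to -0.15 and from -0.31 to -0.14. Of the 9 proliferation genes, 7 had lower values (mean -0.07 ± 0.02, SE, adjusted p = 0.00611 by camera), among them CDC20 at -0.18, CCNB1 at -0.12 and TOP2A at -0.10. With median centring CCNB1 had -0.05. Of the 21 interferon-stimulated genes, 17 had lower values (mean -0.05 ± 0.06, SE, adjusted p = 0.00611), with EIF2AK2 at -0.17 and ISG15 at -0.09. Of the 9 genes of hypoxia and glycolysis, 8 had lower values (mean -0.08 ± 0.02, SE, adjusted p = 0.018), with HIF1A at -0.26, ADM at -0.15 and P4HA1 at -0.11. Each of these 3 genes had both signs on single arrays, and with 1 array left out they ran from -0.40 to -0.11, from -0.24 to -0.06 and from -0.24 to 0.01.

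Without array 3 or 4, the inflammatory list had means of -0.04 and -0.04 and was not called (adjusted p = 0.0508 and 0.289 by camera), and without array 1 its mean was -0.09. Interferon-stimulated genes had -0.01 and -0.02 without array 1 or 4 (adjusted p = 0.966 and 0.838 by camera), and -0.09 and -0.10 without array 2 or 3, with the call kept (adjusted p = 0.00462 and 4.9e-08 by camera). Proliferation and hypoxia and glycolysis lost their calls with means nearer to those of 4 arrays. These were -0.06, -0.08 and -0.07 for proliferation without array 1, 2 or 4 (adjusted p = 0.334, 0.122 and 0.218 by camera). They were -0.08, -0.06 and -0.08 for hypoxia and glycolysis without array 2, 3 or 4 (adjusted p = 0.122, 0.0513 and 0.185 by camera). All 4 lists lost their calls in separate channels (adjusted p = 0.103 to 0.529 by camera). Hypoxia and glycolysis was called in 9 of 14 planned settings, and lost its call also without an offset, with the scanner software's log ratio, in the series matrix and with median centring (adjusted p = 0.0573, 0.0519, 0.09 and 0.25 by camera). The inflammatory list was not called with median centring either (adjusted p = 0.0613 by camera). Beside these lists, the mean ratios of the cell-type markers were 0.01 for macrophages, 0.01 for fibroblasts and pericytes, 0.02 for endothelial cells, -0.02 for lymphocytes and -0.03 for folliculostellate cells, none called.

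Of the other lists, cholesterol synthesis and uptake had lower values for 6 of 6 genes (mean -0.06, adjusted p = 0.0752 by camera, called in 2 of 14 planned settings), with STARD4 at -0.18 and NSDHL at -0.04. Its mean ran from -0.07 to -0.003 over these settings and from -0.11 to -0.02 with 1 array left out. Fatty acid synthesis had higher values for 10 of 12 genes (mean 0.04), with SREBF1 at 0.08. Its means on arrays 1 to 4 were 0.23, -0.18, 0.16 and -0.06, above 0 only with treated RNA in Cy5. With 1 array left out the fitted mean of this list ran from 0.01 to 0.07. The means were 0.02 for fatty acid oxidation and PPAR targets (CPT1A at 0.15), 0.02 for oxidative phosphorylation, 0.02 for heat shock (HSPB8 at 0.14), 0.02 for the insulin and IGF system, 0.03 for releasing hormone and dopamine receptors, 0.01 for steroid, activin, insulin and leptin receptors and 0.02 for markers of the posterior lobe and nervous tissue. They were -0.01 for adiponectin receptors and signalling, -0.03 for hormone secretion and granules, -0.02 for endoplasmic reticulum stress and amino acid response, -0.003 for oxidative stress, -0.001 for pituitary lineage transcription factors, -0.001 for immediate early genes and -0.01 for extracellular matrix remodelling. For extracellular matrix remodelling (median 0.02) and the lineage transcription factors, camera, which used genes measured on all 4 arrays, had the direction higher. The 1 tested marker of red blood cells, HBE1, had a ratio of 0.04.

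Within the lists, 0 of 266 tested genes passed the threshold over all probes, and 13 had an unadjusted p under 0.05. Adjusted over the list alone, 1 gene passed, the immediate early gene KLF6 (adjusted p = 0.0455), with a ratio of 0.35 from 3 arrays whose values were -0.21, 0.01 and 0.80. Only 2 of its 4 tested probes were above 0. Over the planned settings with 4 arrays its ratio ran from 0.02, with the mean of its probes, to 0.53, with median centring. With 1 array left out the ratio of KLF6 ran from -0.19 to 0.35, and it was below 0 without array 1, 3 or 4. In those fits another probe stood for the gene, since the reported one has no value on array 2. The turned signs thus come with a change of probe and do not show how the reported probe depends on single arrays.

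**Figure D2:**
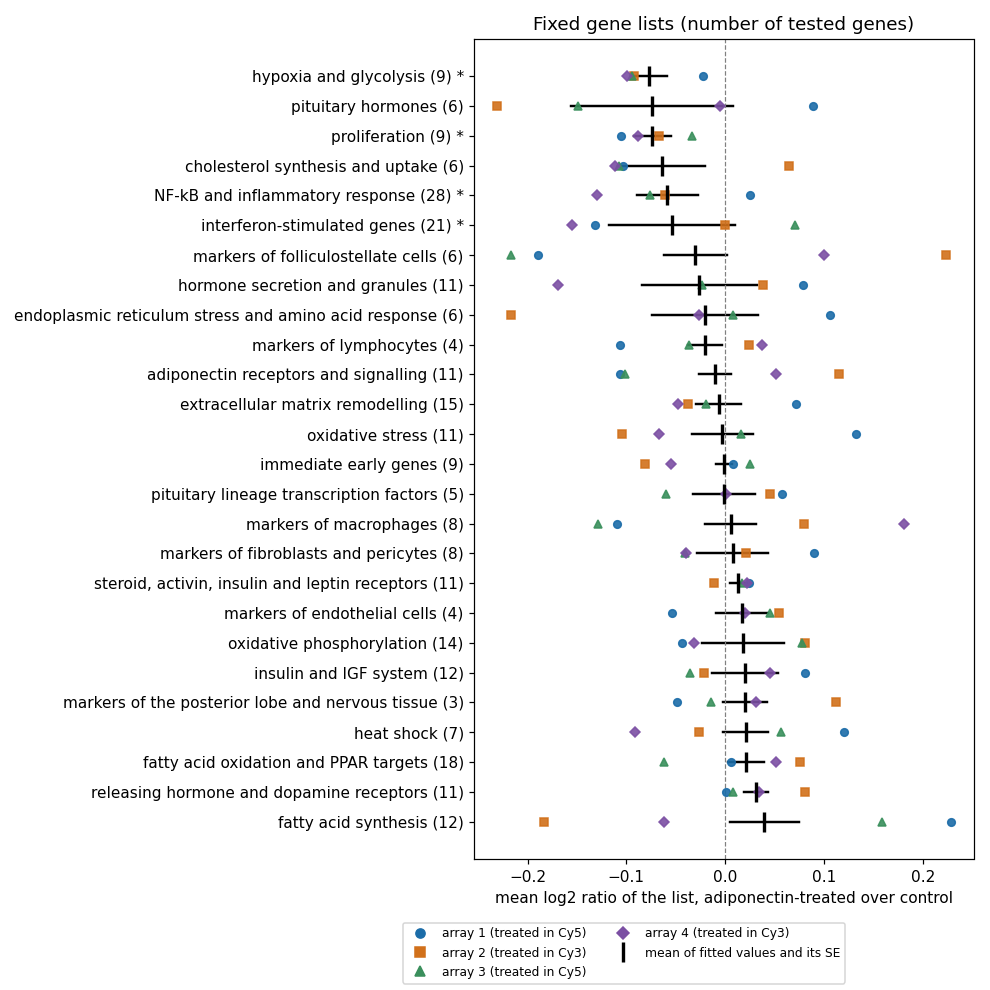
Mean log2 ratio of adiponectin-treated over control cells (horizontal axis) for the 26 tested gene lists, with the number of tested genes in brackets; symbols are the mean of the list on single arrays, black bars the mean of the fitted values with its standard error, and an asterisk marks an adjusted p under 0.05 by camera with the preset correlation. The 4 marked lists have means from -0.08 to -0.05, and of these only proliferation and hypoxia and glycolysis lie below 0 on every array.

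The agreement of the arrays was compared last, across probes, which are not independent replicates. Treated over control ratios correlated positively between arrays of the same dye orientation (mean r = 0.41, 2 pairs) and negatively between arrays of opposite orientation (mean r = -0.46, 4 pairs). As red over green ratios, all 6 pairs were thus positive, from 0.26 to 0.57. The SD across probes was 0.16 for the mean of red over green ratios and 0.07 for the adiponectin term. The remaining contrasts of the 4 arrays had SDs of 0.09 and 0.08.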

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

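All tests in this part were chosen after the results were seen. Among 148 genes and gene lists with 4 array values, 7 had 1 array far from the other 3, where chance gives about 7.4 (1 in 20). On array 4, HOPX had 0.38 (others 0.13 to 0.16), RPL10 -0.0168 (others -0.19 to -0.18), IGFBP6 -0.0173 (others 0.11 to 0.12) and ADAMTS1 -0.83 (others 0.06 to 0.08; its other probe had a fitted ratio of 0.01, against -0.15, and the planned settings ran from -1.07 with the scanner software's log ratio to 0.01 with the strict filter, which leaves the other probe). LCK had -0.0584 on array 3 (others 0.02 to 0.03). The mean of the cholesterol list was 0.0649 on array 2 (others -0.11 to -0.10), and that of hypoxia and glycolysis was -0.0221 on array 1 (others -0.10 to -0.09).

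Red over green ratios correlated between arrays of opposite orientation, with a mean r of 0.46. If this were wholly a treatment effect, with treated RNA in Cy5 on every array, probes of 1 gene should share it at least as well as they share the smaller contrasts. Their correlation was 0.20 in the dye contrast, with an upper bootstrap limit of 0.26, below the lowest limit of the other contrasts (0.36), which argues against that as the whole cause and is consistent with dye bias of single probes. Whether treatment forms part of it cannot be told apart from dye, since both then share 1 term; read that way, 2331 probes passed the threshold. No biological explanation was tested here.

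For the inflammatory list and interferon-stimulated genes, the calls by the preset correlation may come from members that vary together, with estimated correlations of 0.07 and 0.32 against the preset 0.01. For proliferation and hypoxia and glycolysis the estimates were -0.08 and -0.08, so there the loss of the call came from the residual degrees of freedom. The smallest adjusted p with an estimated correlation was 0.879, in a test that recovered a planted shift in 0 of 20 simulations, so the loss decides nothing. Fewer macrophages in treated cultures would lower their markers, whose mean was 0.00561 (95% interval -0.11 to 0.12), an interval that also holds the mean of the inflammatory list. These explanations and an effect of adiponectin stay open, since 2 residual degrees of freedom keep the intervals wide. Only 3 splits of the 4 arrays are balanced for dye, too few for a share under 0.05: the real split called 4 lists, 1 split did so, and the highest other count was 1.

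The same 3 splits bear on the probe counts. At an adjusted p under 0.05 the real split gave 0 and the highest other 0; any split gives at least 0, so the 3 of 3 that gave as many carry no information. At an unadjusted p under 0.05 the real split gave 717 and the highest other 1811, and again 3 of 3 gave as many. The splits are too few for a share under 0.05.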

How the results depend on the processing

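Of these tests, treated RNA taken as Cy5 on every array and normexp fitted on all spots were chosen after the data were seen, as was leaving out spots of uneven background in the values reported. The count of 0 probes stayed 0 under every planned setting with 4 arrays at an adjusted p under 0.05 or 0.10, and with normexp fitted on all spots. It was 108 at an unadjusted p under 0.05 with a fold of at least 1.2, 2331 with treated RNA taken as Cy5 on every array, and 0 to 828 with 1 array left out. The 2 highest counts, 720 and 828, are those whose residual spread comes from arrays 1 and 3 alone, with a median absolute deviation from the mean of the pair of 0.06, against 0.09 for arrays 2 and 4. Genes past the threshold within the lists numbered 27 with treated RNA as Cy5 and 0 to 13 with 1 array left out, and 0 otherwise. Called lists numbered 4, with 3 to 6 under the other planned settings on 4 arrays except for 0 without the array pairing (separate channels, no replicate block), 0 with treated RNA as Cy5, 6 with normexp on all spots and 1 to 3 with 1 array left out. The block moved no probe call. With normexp on all spots, cholesterol synthesis and uptake, fatty acid synthesis and oxidative phosphorylation were called and hypoxia and glycolysis was not. The mean r between arrays of opposite orientation was -0.46, and -0.30 with the scanner software's log ratio, -0.33 with the series matrix, -0.41 without an offset, -0.43 with median centring, -0.43 without a filter, -0.44 with normexp on all spots and -0.47 to -0.46 with 1 array left out. The inflammatory list had a mean of 0.00746 with median centring, which gave all tested probes a median of 0.03 and hypoxia and glycolysis a mean of -0.00247, so the sign says little about this list. With treated RNA as Cy5, it turned to 0.0305, interferon-stimulated genes to 0.0234, proliferation to 0.00425 and hypoxia and glycolysis to 0.0188, and among named genes KLF4 turned to 0.29, RACK1 to 0.40, DDX58 to 0.32, NR3C1 to -0.29, ATF4 to 0.26 and HSP90B1 to 0.23. In the reported values, 1 of 3 probes of NR3C1 and 3 of 4 of RACK1 had the opposite sign. Over all alternatives, 2415 of 2542 comparisons of a named gene stayed within the spread of the arrays, 95 moved further and 26 passed the threshold in the same direction. The cause of these moves was not tested. Some settings, such as the eBayes options, cannot move a ratio, and the spread of the arrays includes dye bias. A sign that turned within that spread was not counted apart, so the tally says little about stability. No spot was saturated, so leaving saturated spots out moved nothing. CGA, lost to uneven background, had a ratio of -0.07 (95% interval -0.24 to 0.11) with outlier-flagged spots kept. Between 25174 and 29845 probes per channel were well above background, which limits what dimmer transcripts can show.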

Other observations

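All tests in this part were chosen after the results were seen, and its genes lie outside the rule for named genes unless given in the report. Among 467 genes with at least 3 tested probes, 214 had probes of 1 sign. The other dye-balanced splits of the arrays gave 205 and 175, so probes of 1 sign do not mark a response. The highest mean was that of SPARCL1, a matricellular protein gene, at 0.38 with 7 of 7 probes above 0, followed by SELENOP, a selenium transport protein gene, at 0.22 (10 of 10), and AMY2 had 0.19 (23 of 23). The means of SPARCL1 on arrays 1 to 4 were -0.18, 1.03, -0.03 and 0.71, so it was above 0 on the arrays with treated RNA in Cy3 alone. With treated RNA taken as Cy5 on every array it was below 0 on each (median over its probes -0.48), so its direction rests on the channel labels. The probe means of SELENOP were high on array 2 alone (0.90, others -0.08 to 0.05). The median dye term of the probes was -0.21 for SELENOP and 0.13 for AMY2, so the direction of SELENOP rests on the channel labels too. On the lower side were MYC at -0.19 (3 of 3 probes), P4HA1 at -0.18 (6 of 6), HSP90B1 at -0.12 (8 of 8) and CHGB, which encodes a secretory granule protein, at -0.11 (13 of 13). In that order the median dye terms of their probes were 0.09, 0.16, 0.03 and 0.05, so these directions rest on the channel labels. With median centring the brightest probe of CHGB had 0.02. The probe means varied over single arrays, whose values hold dye bias that the fitted values do not. On arrays 1 to 4 they were 0.12, -0.20, -0.17 and -0.47 for P4HA1 and 0.06, -0.15, -0.28 and 0.002 for CHGB. Those of MYC ran from -0.34 to 0.03 and of HSP90B1 from -0.25 to -0.0003. No probe of these genes had an adjusted p under 0.05.

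More fibroblasts and pericytes in the treated cultures could raise SPARCL1, SELENOP and AMY2 together, as a hypothesis. The markers of these cells would then be higher by about as much. The upper 95% limit of their mean was 0.163, below the smallest mean of these genes. The means of the genes vary over the arrays (SD 0.58, 0.46 and 0.15 in that order), but these SDs include dye bias, which the limit of the markers does not. No interval was computed for the fitted means of the genes, so this comparison cannot decide it. This hypothesis and an effect of adiponectin stay open. The 3 dye-balanced splits are too few for a share under 0.05: the real split gave 4 genes with probes of 1 sign as far from 0, the highest other gave 5, and 2 of 3 splits gave as many.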
